A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

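The 4 arrays are 1 each of Rec10 immunoprecipitate against whole-cell input in wild type and clr4Δ at 0 h and 3.5 h of meiosis, grouped by the genotype and time in the labels. Per the labels' protocols, cells were starved of nitrogen to synchronise them, nitrogen was then given back and the temperature raised to start meiosis, chromatin was fixed with formaldehyde and sheared, and the precipitated DNA was amplified by PCR while Cy3 or Cy5 was built in. Amplification can favour some sequences over others, which cancels in a difference between arrays only if it was equal on them. Scanner files and the authors' value table were used.

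The scanner files give intensity per probe, which per the file headers was quantified with Agilent Feature Extraction 10.7.3.1. Per the file headers, processed intensities were background-subtracted, spatially detrended and dye-normalized within each array with a linear factor, and were not scaled between arrays. The deposited log10 ratio of each scanner file is red (Cy5) over green (Cy3). Per the file headers, the array design is Agilent-025249 and its annotation the genome build Sp2002:NCBI1.1:Feb2002, whose coordinates were not used. The authors' value table holds log10 ratios after dye swap correction and centring on the genome's median, per the series' design text. It holds 43766 probes, without 66 probes of the scanner files, among them all mitochondrial ones. Set against each scanner file, the authors' values had a slope of -1.0 and medians of 0.0 on all 4 arrays, so their scale, centring and direction are known, apart from departures of up to 0.0817 at single probes. No column of the files was left without a sample (0 columns).

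Values here are log2 of processed Cy3 over processed Cy5 intensity, centred on the median of all non-control probes of the array, without loess or quantile normalization. The plan made before the data were examined had Cy5 over Cy3, from the dye labels, with the turned sign as an alternative. The turned sign was taken as the main direction once the comparison with the authors' table had shown theirs. In the direction planned first, each signed value changes its sign, and sizes and percentiles below or above the windows exchange sides. All 4 arrays share 1 scanning session in the file headers, so no batch could be split.

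Probe sequences were matched exactly, on both strands, to assembly ASM294v3, and all coordinates are of that assembly. Of 43832 probes, 42917 matched 1 site, 908 several (at most 51) and 7 none. The reference names no centromere, so each centromere is the longest interval without a protein-coding gene on its chromosome: I 3751730 to 3790923 (per1 to emc5), II 1596745 to 1648231 (rpb1 to yox1) and III 1064444 to 1142615 (meu27 to ppc1). Inside them, probes with several sites stand for repeats. Central domains (I 3765008 to 3777265, II 1618293 to 1630122, III 1092437 to 1106557) and outer segments were bounded by clusters of tRNA genes more than 12 kb apart, a choice made after the data were examined, as were the mat3 interval, the tRNA neighbourhoods of 500 bp and the limit of 0.5 for counting genes. In centromere I no tRNA gene lies to the right of the central domain. The right outer segment there runs to the interval's end at 3790923. Of the mating-type region the reference holds only mat3 genes, and other parts were not analysed here. Flanks are 50 kb on either side of a centromere and subtelomeres 100 kb from each chromosome end.

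A region's value is its median over probes. Its percentile is among 10000 random windows of the same number of consecutive arm probes. A gene's value is the median over at least 3 probes in its body (4575 genes). A list's percentile is among 10000 random lists of the same size matched on brightness. Values outside percentiles 2.5 to 97.5 are described as outside the central range; with 5 contrasts and 13 lists some would fall there by chance. Domains are defined in the report, and shared means at least 1 probe in common. Named genes follow a rule written before the data were examined: per contrast the 10 highest and 10 lowest genes with at least 3 probes, all well above background and at least 80% of them on the same side, the 10 highest domains of wild type 3.5 h, and members of the lists. The lists were linear elements and break formation, cohesin, early meiosis regulators, middle meiosis, heterochromatin machinery, kinetochore and pericentromere protection, heterochromatin islands, housekeeping genes, cytosolic ribosomal proteins, histones, hotspot genes, Tf2 retrotransposons, nitrogen starvation genes and tRNA genes. None of 171 tRNA genes had 3 probes in its body, so probes near them were used. Highly transcribed genes and mitochondrial probes served as markers of technical signal.

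The gene and domain steps were tested on simulated data before use. For clr4Δ 3.5 h minus wild type 3.5 h with 4575 genes, 190 of 200 genes shifted by 1.0 were recovered (95.0%) and 384 unshifted genes (8.78%) passed the limit of 0.5, in a simulation that removed the signal the arrays share. With 50 domains planted on independent noise, 50 were called, compared by number and not by position. Neighbouring probes of the arrays correlate and many of their domains were weaker than the planted ones. The test therefore says little about missed or false domains on the arrays. Alternatives were normexp background correction (offset 50), loess within each array (span 0.3), centring on arm probes, scaling arrays to one median absolute deviation, filters on dim, non-uniform and several-site probes, means in place of medians, the authors' value table, each centromere left out, other flank sizes, other domain settings, single probes matched on brightness in place of windows, and the turned sign. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used. With 1 array per group, no test between groups was run.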

Results

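The series measured where Rec10 lay on the genome of the fission yeast Schizosaccharomyces pombe in early meiosis. Rec10 is a component of the linear elements, the protein axes that form along fission yeast chromosomes in meiotic prophase and on which recombination depends. Crosslinked chromatin was precipitated with an antibody against GFP and hybridised together with whole-cell input DNA to a 2-colour Agilent tiling array (ChIP-chip). Wild type was compared with clr4Δ, which lacks the histone H3 lysine 9 methyltransferase Clr4 on which heterochromatin depends, at 0 h and 3.5 h of meiosis. The series' title names the repression of meiotic recombination near centromeres as its subject, so the regions of interest were the centromeres, with the chromosome arms as the background. Each of the 4 groups (wild type 0 h, wild type 3.5 h, clr4Δ 0 h, clr4Δ 3.5 h) held 1 array. No difference between groups therefore has a replicate check, no p-value is given, and each SD describes the spread over probes or genes within arrays. The number of arrays limits the precision of every value.

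Each array carried 43832 probes of 45 to 60 bases. Median probe brightness before background subtraction and dye normalization was 10944 in Cy3 and 14710 in Cy5 for wild type 0 h, 19321 and 17342 for wild type 3.5 h, 11352 and 11140 for clr4Δ 0 h, and 17223 and 14759 for clr4Δ 3.5 h. Median local backgrounds lay between 21.5 and 25 in Cy3 and between 84.0 and 85.5 in Cy5, no probe was saturated, and 1 probe was not well above background (Cy5, clr4Δ 3.5 h). Neighbouring probes correlated more strongly on the 3.5 h arrays (r = 0.838 in wild type, 0.689 in clr4Δ) than on the 0 h arrays (0.595 and 0.618). Over probes, the ratios of the 3.5 h arrays correlated with each other (r = 0.799), and those of the 0 h arrays only weakly (r = 0.194).

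All values below are log2(Cy3/Cy5) with the array's median set to 0, which is the direction of the authors' own value table. The labels place input in Cy3 and the immunoprecipitate in Cy5, but add that the dyes were swapped. Read literally, the Cy3 and Cy5 labels give every signed value the opposite sign. That Cy3 held the immunoprecipitate is likely, on 4 grounds. The authors' table turns the scanner's log ratio on every array (r between -1.0 and -0.99954), and the Cy5 channels, as a common genomic input would, resembled each other more (r between 0.889 and 0.944 over 6 pairs) than the Cy3 channels (0.725 to 0.888). The 3.5 h ratios were skewed upwards (skewness 1.17 in wild type, 0.26 in clr4Δ), although the 0 h ratios were skewed downwards (-0.17 and -0.98), which makes this ground weak, and single-site probes formed 60 and 19 runs at or above 1 on those arrays but 0 runs at or below -1 on any array. The ratio is called the Rec10 ratio from here on, although no array of an untagged strain or mock precipitate was among the 4, so its non-specific part was not measured.

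The deletion was visible in the DNA on both clr4Δ arrays. Of the 15 probes in clr4, 5 probes (chromosome II, 456824 to 458019, assembly ASM294v3, inside the gene) were nearly dark in clr4Δ. Their median difference from wild type was -8.42 in Cy3 and -7.12 in Cy5 at 0 h, and -8.03 and -8.78 at 3.5 h. The other clr4 probes lay outside the lost part, with medians of -0.29 to 0.13, and check nothing.

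Whether Rec10 moved onto chromosomes between 0 h and 3.5 h was asked first in wild type. At 3.5 h the Rec10 ratio stood in short, sharp peaks on the arms, many of them between genes, which the 0 h array did not show. In the same comparison the repeats around the 3 centromeres read lower at 3.5 h than at 0 h, while the central domains of the centromeres stayed close to their 0 h values. The highest peaks lay over SPAC1834.13 and pex7, a peroxisomal import receptor gene, in the gap between SPAC24H6.13 and uba3, between rps1801 and the transcription factor gene mbx2, over SPBC3E7.17 and ric8, and beside ste11, the regulator that commits cells to sexual differentiation.

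A domain was defined as at least 4 consecutive single-site probes, neighbours at most 2 kb apart, at 1 or more after a running median of 3 probes. Wild type 3.5 h had 60 domains with a median length of 1379 bp, holding 0.903% of 41328 arm probes, and wild type 0 h had 0. Over these 60 domains the median ratio was 1.42 (SD 0.30 over domains) in wild type 3.5 h and 0.04 (SD 0.19) in wild type 0 h. Of the 57 domains on the arms, 17 domains (29.8%) had no probe inside a protein-coding gene, against 3.4% on average for random windows of the same sizes and 14.0% in the highest of 1000 draws. In falling order, the top 10 domains lay at I 4721438 to 4722959 (SPAC1834.13 and pex7, 2.27), I 460008 to 461480 (no gene, 2.06), II 3623177 to 3625710 (no gene, 2.03), II 2661061 to 2662501 (SPBC3E7.17 and ric8, beside the heat shock gene hsp16, 1.97), II 3979997 to 3983417 (the gap between cyc3 and ste11 with the edge of ste11, 1.97), I 2663571 to 2665552 (mug114, 1.93), I 103512 to 104875 (pdc101 and SPAC1F8.08, 1.92), II 4471171 to 4472594 (no gene, 1.88), II 1572751 to 1574329 (sua1 and mep33, 1.86) and II 4442382 to 4444095 (no gene, between ecl3 and the phosphate transporter gene pho84, 1.84). Normexp raised all 10 (2.74 to 3.44) and changed their order, with mug114 (3.44) and ste11 (3.43) first and SPAC1834.13 with pex7 (2.74) last. Over the probes of the ste11 domain the SD was 0.44, and the ste11 body itself (II 3983376 to 3987400, 14 probes) read 0.02 in wild type 3.5 h and 0.31 in wild type 0 h.

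**Figure D1:**
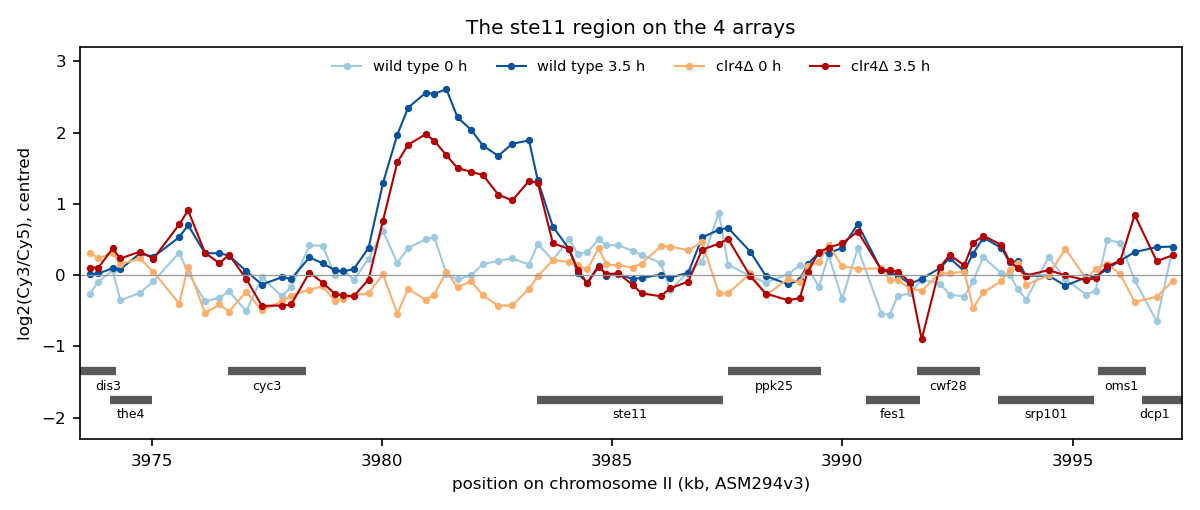
The Rec10 ratio (log2(Cy3/Cy5), centred, vertical axis) of each probe along chromosome II around ste11 (position in kb, ASM294v3, horizontal axis), 1 line per array, with genes as grey bars. Both 3.5 h lines stand above 1 over most of the domain at 3979997 to 3983417, whose median was 1.97 in wild type 3.5 h and 1.45 in clr4Δ 3.5 h, against 0.20 in wild type 0 h and -0.19 in clr4Δ 0 h.

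Of 4575 genes with at least 3 probes in their body, 106 genes were higher by at least 0.5 at 3.5 h than at 0 h in wild type and 30 genes were lower by as much, a balance that turned under normexp background correction (217 and 308). The lower count was 15 without several-site probes, 17 with means and 48 with arrays scaled to one spread. The highest were SPAC1834.13 (2.33, SD 0.21 over 4 probes), mug114 (2.01, SD 0.36), SPAC56F8.13 (2.01, SD 0.60), SPAC1F8.08 (1.93, SD 0.23), the thiamine synthesis gene nmt1 (1.93, SD 0.71) and the adenine synthesis gene ade6 (1.64, SD 0.64), known for its recombination hotspot alleles. SPAC343.21 (1.56), mug115 (1.25), mug155 (1.22) and SPCC1235.17 (1.20) followed. SPAC56F8.13 lies inside mug115 (I 1148131 to 1151250), so these are 1 site. Lowest were ure4 (-0.73, SD 0.39), cue1 (-0.68, SD 0.10), the galactosyltransferase gene gma12 (-0.67, SD 0.11), emc10 (-0.63), atp11 (-0.59), rgs1 (-0.57) and rav2 (-0.56), each of which was high at 0 h (0.44 for cue1 to 0.84 for ure4) and lay between -0.24 and 0.10 at 3.5 h. The repeated subtelomeric genes SPBC1348.01, SPBCPT2R1.04c (both -0.57) and SPBCPT2R1.01c (-0.55) made up the rest of the 10 lowest, and loess brought these to -0.26, -0.24 and -0.23. Under normexp the 10 highest moved up, to 1.88 (mug115) to 3.61 (SPAC1834.13).

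At the centromeres, probes that match several genome sites differed between wild type 3.5 h and 0 h by -0.52 on centromere I (SD 0.39, 175 probes), -0.55 on centromere II (SD 0.23, 170 probes) and -0.55 on centromere III (SD 0.29, 188 probes). All 3 lay below each of 10000 random arm windows of the same number of probes. The centromeres share many of these probes, which number 273 in all, so they are not independent. In wild type 3.5 h the 3 medians were -0.90, -1.07 and -1.07. The outer segments, bounded mainly by tRNA genes after the data were examined, differed by -0.56 (SD 0.24, 195 probes), which is 0.68-fold. The difference was -0.31 without centromere III, -0.22 under loess and -0.18 on the 15 single-site probes alone. The central domains differed by 0.02 (SD 0.28, 110 probes). The 50 kb flanks on either side of the centromeres differed by -0.04 (SD 0.35, 1067 probes, percentile 11.6 among windows but 0.01 among single probes matched on signal). Single probes leave out the correlation of neighbouring probes. Percentiles among them, here and below, thus come from a range that is too narrow for a region. Subtelomeres, the 100 kb at each chromosome end, differed by -0.12 (SD 0.40, 1768 probes, percentile 0.00). Probes with sites in several ends enter only this pooled value. On the probes of single ends the difference was -0.25 at II left and -0.20 at I right, and no other end lay outside the central range of windows (percentiles 2.5 to 97.5). The interval around mat3, a silent copy of mating-type information, up to the neighbouring genes (II 2128468 to 2138318, 37 probes with those of mat3), differed by 0.24 (SD 0.28, percentile 95.7, and 100 among matched single probes). The mat3 genes alone differed by -0.14 (SD 0.05, 5 probes), a direction that loess turned (0.18) and normexp weakened (-0.0576). All 5 probes match several sites, so each value of the mat3 genes also reads another genome site. Mitochondrial probes, a marker of technical signal, differed by 0.35 (SD 0.15, 61 probes), and by 0.66 under normexp and 0.93 under loess.

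Among the gene lists fixed beforehand, Tf2 retrotransposons stood lower at 3.5 h than at 0 h in wild type by -0.49, with 13 of 13 elements below 0 (percentile 0.00 among 10000 matched random lists). Their elements share most probes and count as about 1 measurement, with an SD of 0.01 over elements. Random lists hold separate genes. In wild type 3.5 h their central range was -0.29 to -0.06, against -0.83 for the brightest single-site arm probes. The random lists may thus be dimmer than Tf2. No percentile of Tf2, here or below, separates Tf2 from bright, shared probes. Histone genes stood higher by 0.22 (SD 0.35 over 5 genes, 3 of 5 above 0, percentile 99.0). Lists that stayed inside the central range of random lists were linear elements and break formation (-0.02, 4 of 10 above 0), cohesin (-0.11, 1 of 8), early meiosis regulators (-0.01, 3 of 8), middle meiosis genes (-0.04, 4 of 8), heterochromatin machinery (-0.08, 3 of 13), kinetochore and pericentromere protection (0.02, 4 of 7), heterochromatin islands (-0.03, 3 of 6), housekeeping genes (0.04, 9 of 15), cytosolic ribosomal proteins (0.08, 28 of 50), the hotspot genes ade6, fbp1, ctt1 and cds1 (0.15, 3 of 4) and nitrogen starvation genes (-0.004, 5 of 11). Thus rec10 itself (-0.04 at 0 h, -0.07 at 3.5 h), the cohesin gene rec8 (0.06 and -0.03) and mei2 (0.45 and -0.04) had no raised median over the gene body at 3.5 h. The lists cover gene bodies only, and some members had a wild type 3.5 h domain beside them. Examples are mei2 (I 4515262 to 4516391, 1.47), isp6 (1.16) and mbx2 (2.03). As limits for the repeats, loess within each array brought the differences to -0.23 on centromere II and -0.19 on centromere III and that of Tf2 to -0.03. Single-site probes as bright as the outer segments also read lower at 3.5 h (-0.27, SD 0.33, 118 different probes, some matched more than once).

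**Figure D2:**
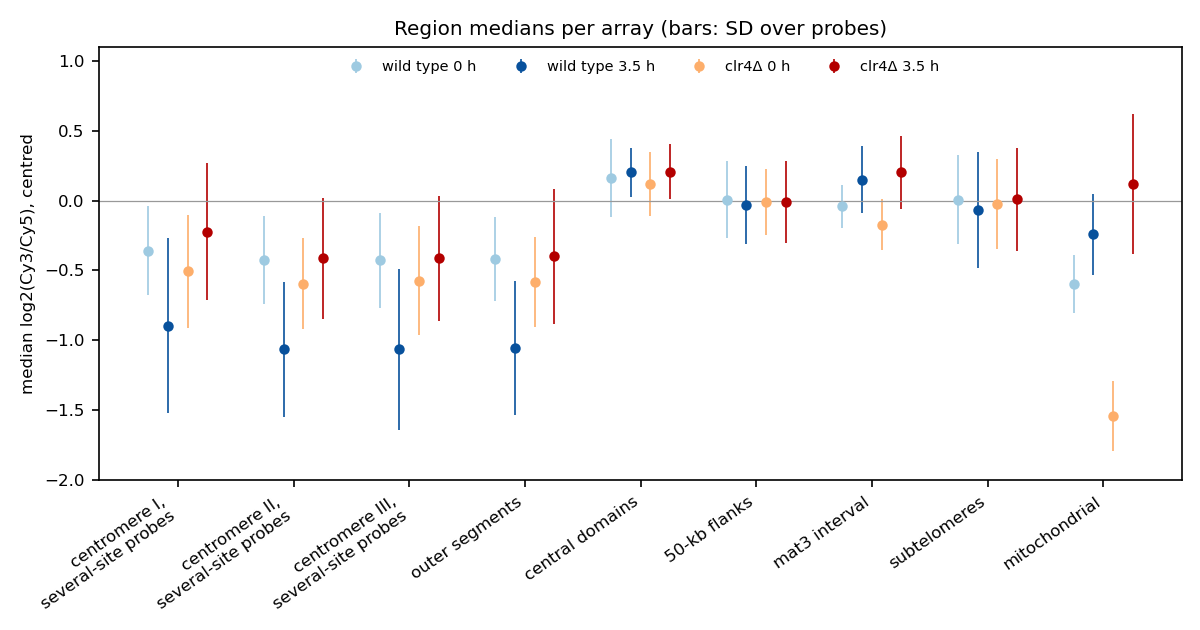
Median Rec10 ratio (log2(Cy3/Cy5), centred, vertical axis) of each region (horizontal axis) on the 4 arrays, with bars for the SD over probes, not replicates. In wild type 3.5 h the outer segments stand at -1.06, below the other 3 arrays (-0.42, -0.58 and -0.40), whereas the central domains lie between 0.12 and 0.21 on all 4.

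The same time comparison in clr4Δ asked what happened without H3K9 methylation. At 3.5 h clr4Δ also had peaks on the arms, the highest again over SPAC1834.13 and pex7 (1.65), but fewer passed the threshold. The repeats around the centromeres, which read lower at 3.5 h in wild type, read higher at 3.5 h than at 0 h in clr4Δ.

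There were 19 domains in clr4Δ 3.5 h, with a median length of 1081 bp and 0.24% of arm probes, and 0 in clr4Δ 0 h. Of 17 arm domains, 6 domains (35.3%) had no probe inside a gene, against 3.9% for random windows. Gene differences of at least 0.5 numbered 61 higher and 16 lower, and under normexp 144 higher and 215 lower. The highest were SPAC1834.13 (2.12, SD 0.17), SPAC56F8.13 (1.90, SD 0.09), mug114 (1.76, SD 0.48), SPBC1105.13c (1.59, SD 0.08), SPAC1F8.08 (1.35), SPCC1235.17 (1.33), ade6 (1.32, SD 0.41), mug115 (1.28), SPAPB15E9.06 (1.25) and SPBC16E9.20 (1.17). The lowest were knh2 (-0.64, SD 0.12), but2 (-0.59), the hexose transporter gene ght7 (-0.58), mde5 (-0.58), rds1 with its overlapping neighbour SPAC343.20 (both -0.58), ish1 (-0.57), pfl2 (-0.54), the tryptophan synthase gene trp2 (-0.54) and esf1 (-0.54). Under normexp SPBC1105.13c read 3.06, SPCC1235.17 2.49 and esf1 -1.18.

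Several-site probes differed between clr4Δ 3.5 h and 0 h by 0.16 on centromere I (SD 0.34, percentile 99.6), 0.21 on centromere II (SD 0.33, percentile 100) and 0.13 on centromere III (SD 0.34, percentile 99.1). For the outer segments the difference was 0.25 (SD 0.34), smaller than its spread over probes, and for the central domains 0.06 (SD 0.26, percentile 80.6). The mat3 interval was higher by 0.40 (SD 0.23, percentile 99.2) and the mat3 genes by 0.26 (SD 0.09, percentile 81.7), which normexp raised to 0.70 and 0.66, and loess the mat3 genes to 0.47. Subtelomeres differed by 0.03 (SD 0.41, percentile 99.6), with 0.21 at I left, and the flanks by -0.004 (SD 0.37). Mitochondrial probes differed by 1.70 (SD 0.44), and this difference came from the clr4Δ 0 h array, whose mitochondrial probes stood 1.34 above the array's median in Cy3, against 2.41 to 2.69 on the other arrays. Among the lists, Tf2 elements were lower by -0.28 (13 of 13), housekeeping genes by -0.15 (SD 0.11, 13 of 15 below 0, percentile 0.42), with pma1, the proton pump gene, at -0.09 and -0.28, and histone genes were higher by 0.17 (SD 0.18, 4 of 5, percentile 98.8). The other 10 lists lay inside the central range, from -0.15 for heterochromatin machinery and cohesin to 0.05 for heterochromatin islands.

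How Rec10 at 3.5 h differed without clr4 is the comparison closest to the series' title. Around all 3 centromeres the repeats read higher in clr4Δ 3.5 h than in wild type 3.5 h, by 1.46-fold over the outer segments, while the central domains differed little. On the arms, every domain picked in wild type, among them those at ade6, nmt1 and mug114, read above 0 in clr4Δ 3.5 h and lower than in wild type. The housekeeping gene adh1 and the other measured housekeeping genes also stood lower.

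Several-site probes were higher in clr4Δ 3.5 h by 0.47 on centromere I (SD 0.30), 0.53 on centromere II (SD 0.25) and 0.48 on centromere III (SD 0.28), each above all 10000 windows. The outer segments differed by 0.55 (SD 0.21, 195 probes) and the central domains by 0.02 (SD 0.17, percentile 75.3). With each of the 273 several-site probes counted once, medians over all 3 centromeres were -0.54 in wild type 3.5 h and -0.04 in clr4Δ 3.5 h. The flanks differed by 0.03 (SD 0.22, percentile 99.7), subtelomeres by 0.08 (SD 0.28, percentile 100), the mat3 interval by 0.09 (SD 0.19, percentile 98.0), the mat3 genes by 0.03 (SD 0.09) and mitochondrial probes by 0.41 (SD 0.48), the last 2 of which loess turned to -0.12 and -0.0893. Of the subtelomeres, I right (0.14) and II left (0.11) lay above all windows. Normexp background correction raised the outer-segment difference to 0.83, and loess brought it down to 0.35.

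**Figure D3:**
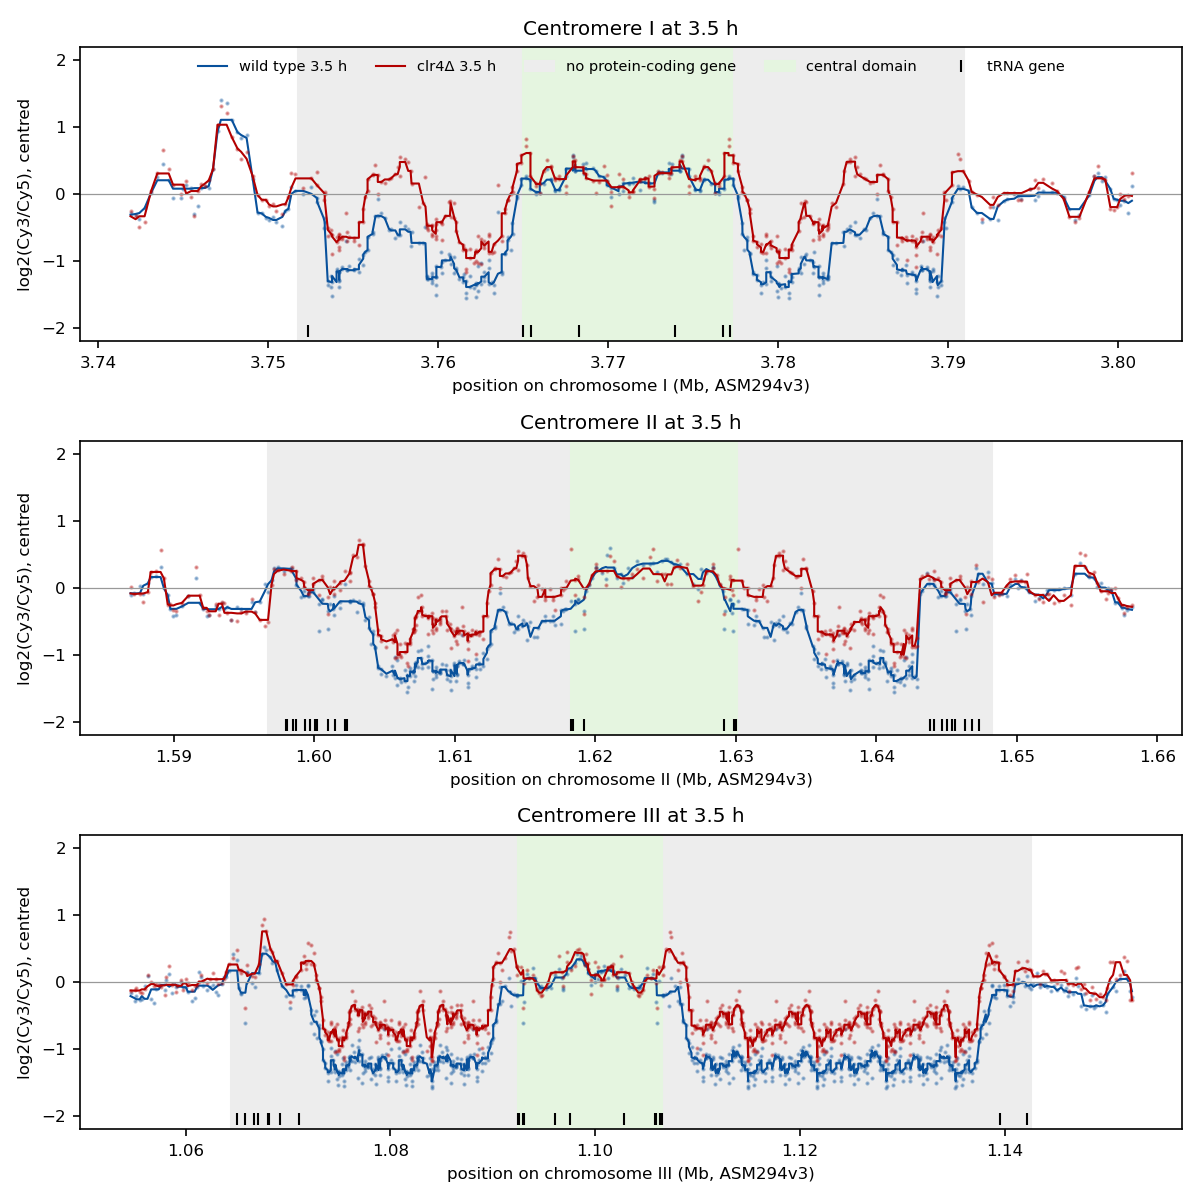
The Rec10 ratio (log2(Cy3/Cy5), centred, vertical axis) along the 3 centromeres (position in Mb, ASM294v3, horizontal axis) in wild type 3.5 h and clr4Δ 3.5 h, with probes as points, running medians of 5 probes as lines, gene-free intervals in grey, central domains in green and tRNA genes as ticks. The lines part over the outer segments (medians -1.06 and -0.40) and run together over the central domains (0.20 and 0.21); probes that match several sites are drawn at each site.

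All 19 domains of clr4Δ 3.5 h shared a probe with a wild type 3.5 h domain, and 18 of the 60 wild type domains shared one with clr4Δ. In the 60 wild type domains the median ratio was 0.91 (SD 0.24) in clr4Δ 3.5 h against 1.42 in wild type, and all 60 were above 0 and lower than in wild type. The choice of domains does not account for this, since in the 19 domains picked on clr4Δ 3.5 h wild type was also higher, with medians of 1.91 and 1.38 (19 of 19). At 0 h the same places already differed in this direction. Medians were 0.04 in wild type and -0.29 in clr4Δ over the 60 domains, and 0.10 and -0.32 over the 19. The gap at 3.5 h is therefore not a difference in the rise over time alone. Counts depend on the threshold, with 174 domains in wild type 3.5 h and 140 in clr4Δ 3.5 h at 0.5, of which 109 and 110 were shared, and 21 and 3 at 1.5.

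**Figure D4:**
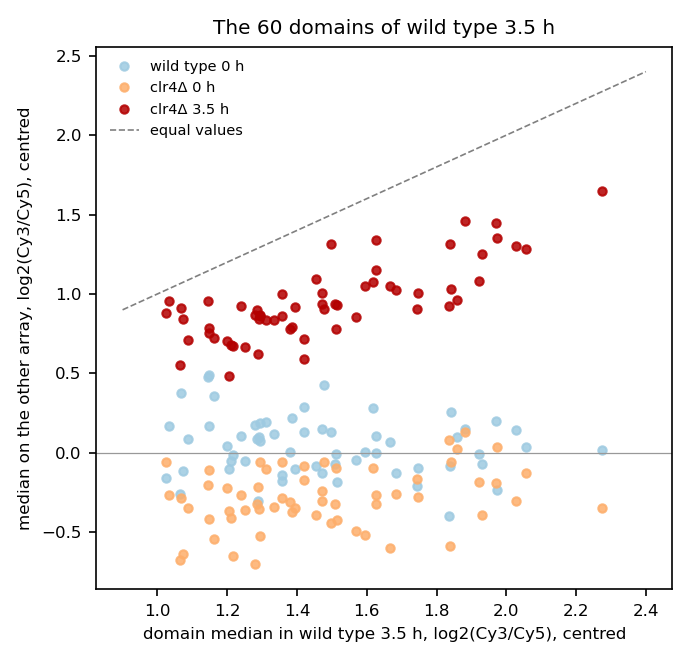
Median Rec10 ratio (log2(Cy3/Cy5), centred) of the 60 domains of wild type 3.5 h on the other 3 arrays (vertical axis) against wild type 3.5 h (horizontal axis), 1 point per domain and array. All 60 clr4Δ 3.5 h points lie above 0 and under the dashed line of equal values, and the 0 h points scatter around medians of 0.04 and -0.29.

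No gene was higher by 0.5 in clr4Δ 3.5 h than in wild type 3.5 h, and 9 genes were lower by as much. Normexp gave 15 genes higher and 39 lower, means gave 4 higher and 15 lower, and arm centring and scaled arrays gave 2 higher each. The remaining settings gave no gene higher. The 9 genes were SPAC1F8.08 (-0.84, SD 0.16), nmt1 (-0.77, SD 0.12), ade6 (-0.75, SD 0.08), mug114 (-0.72, SD 0.18), SPAC1834.13 (-0.63, SD 0.13), mug14 (-0.59), the ATP sulfurylase gene sua1 (-0.58), SPAC343.21 (-0.53) and adh1 (-0.52, SD 0.27). SPBC1105.13c (-0.50) completes the 10 lowest. Sizes depended on background correction, as normexp gave -1.79 for SPAC1F8.08, -1.48 for nmt1, -1.71 for ade6, -1.60 for mug114 and -1.22 for SPAC1834.13. The 10 highest were all subtelomeric genes in which several or all probes match several sites, from SPBC1348.07 and SPAC977.06 (both 0.50, SD 0.11) through SPBCPT2R1.04c and SPBC1348.01 (both 0.39), SPAC212.06c (0.38), SPAC750.06c, SPBCPT2R1.01c and SPAC212.01c (each 0.37) and SPAC212.04c (0.36) to SPBPB2B2.15 (0.35). Loess brought 8 of these 10 down, to 0.20 for SPBC1348.07 and SPAC977.06, 0.0371 for SPAC212.06c and 0.16 to 0.18 for the other 5. Of the lists, Tf2 elements were higher by 0.30 (13 of 13), a call that loess turned to -0.10. Housekeeping genes were lower by -0.13 (SD 0.14, 15 of 15, percentile 0.03), with eno101 at 0.46 and 0.21 and fba1 at 0.44 and 0.12. Of these genes, tdh1 and eno101 overlap wild type 3.5 h domains, so their values are not separate from the domain difference. The 4 hotspot genes were lower by -0.16 (SD 0.33, 4 of 4, percentile 0.41), a list in which ade6 alone reached 0.5. The other 10 lists lay between -0.05 (heterochromatin islands) and 0.03 (cohesin), inside the central range.

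The same genotypes at 0 h, when neither had a Rec10 domain, show how far arrays differ without them. At 0 h the repeats around the centromeres read lower in clr4Δ than in wild type, the opposite of 3.5 h. Single genes differed in both directions, from the splicing factor gene sap114 (higher in clr4Δ) to SPBC1105.13c (lower).

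Several-site probes differed between clr4Δ 0 h and wild type 0 h by -0.15 on centromere I (SD 0.24, percentile 0.11 among windows but 3.63, inside the central range, among matched single probes), -0.21 on centromere II (SD 0.20) and -0.19 on centromere III (SD 0.22). The outer segments differed by -0.20 (SD 0.21), the central domains by -0.06 (SD 0.31, percentile 18.3), the flanks by -0.02 (SD 0.34), subtelomeres by -0.06 (SD 0.34, percentile 0.00), the mat3 interval by -0.11 (SD 0.22, percentile 16.6) and the mat3 genes by -0.34 (SD 0.06, percentile 9.27). Mitochondrial probes differed by -0.96 (SD 0.18), the largest of the region differences at 0 h. Counts at 0.5 were 69 genes higher and 66 genes lower, and 258 and 242 under normexp. The highest were sap114 (1.01, SD 0.48), the polymerase subunit gene rev7 (0.84), cdh1 (0.74), slu7 (0.72), ckb1 (0.71), the proteasome gene pre4 (0.71), whi5 (0.70), pga3 (0.69), ppk13 (0.69) and csn4 (0.66), of which normexp brought sap114 to 0.49, under the limit, and rev7 to 0.57. Among the lowest were SPBC1105.13c (-0.99, SD 0.12), SPBC83.12 (-0.92), mlo3 (-0.91), ddr48 (-0.89), the glutaredoxin gene grx1 (-0.88), bur6 (-0.88), SPAC11D3.04c (-0.86), emc10 (-0.80), ure4 (-0.78) and dad5 (-0.76, and -0.41 under normexp). None of the 13 lists lay outside the central range at 0 h, the nearest being early meiosis regulators (-0.13, 5 of 8 below 0, percentile 2.91) and hotspot genes (-0.21, 3 of 4 below 0, percentile 4.74).

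Whether the change from 0 h to 3.5 h differed with clr4 is given by the difference of the 2 changes. Among chromosomal regions it was largest over the centromere repeats, where wild type read lower and clr4Δ higher at 3.5 h than at 0 h, and near 0 over the central domains. The difference was 0.63 on centromere I (SD 0.47), 0.69 on centromere II (SD 0.34), 0.66 on centromere III (SD 0.42) and 0.75 over the outer segments (SD 0.32), each above all 10000 windows, against 0.03 in the central domains (SD 0.34, percentile 71.3). The flanks (0.03, SD 0.38, percentile 88.8), the mat3 genes (0.40, SD 0.13, percentile 92.3) and the mat3 interval (0.19, SD 0.30, percentile 95.8) lay inside the range of windows. Subtelomeres (0.14, SD 0.47) and mitochondrial probes (1.39, SD 0.47) lay above it. Against matched single probes, which ignore the correlation of neighbours, the flanks reached 99.9 and the mat3 interval 99.1. Tf2 elements gave 0.22 (percentile 99.3, with the limit given above for Tf2), which loess turned to -0.38, and no other list lay outside the central range. Of single genes, picked by the same rule after the values were seen, bur6 (0.89), grx1 (0.85) and ure4 (0.84) were highest and nmt1 (-1.26), sap114 (-1.01) and meu43 (-0.90) lowest. For sap114 the difference came from the 0 h arrays, with -0.94 in wild type 0 h and 0.07 in clr4Δ 0 h.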

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

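Of the tests below, those of the first pattern on brightness and on GC content and that of the third pattern on the scaled domain threshold were set before their result was seen; the others were chosen only afterwards.

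Between 0 h and 3.5 h the median Rec10 ratio went down in wild type and up in clr4Δ over several-site probes of centromere I, centromere II and centromere III, with differences of the changes of 0.63, 0.69 and 0.66. The same opposite changes appeared over all centromeric several-site probes (0.60), the outer segments (0.75) and the subtelomeres (0.14). Each group had 1 array, so none of these 6 differences was tested. Besides clr4, 2 probes of the gene mal1 (chromosome II, 154055 to 154274) were nearly dark in clr4Δ in both channels, with Cy5 differences of -7.23 at 0 h and -10.18 at 3.5 h against -0.06 and -0.10 for the other mal1 probes. Mitochondrial probes, which enter no comparison of chromosomes, differed by -0.96 between clr4Δ 0 h and wild type 0 h.

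The first pattern is the low level of the outer segments in wild type 3.5 h (-1.06). GC content of the probes is argued against, since single-site arm probes of equal GC read -0.0288 (SD 0.35). Brightness and probes with several sites stay open. Single-site probes of like brightness outside the centromeres read -0.76 (SD 0.49). They are 118 different probes matched to 195 outer-segment probes, some of them more than once. The 634 several-site probes outside the centromeres read -0.51 (SD 0.44). Neither set was limited to the arms, and the several-site set includes subtelomeric probes. These values therefore do not separate a property of such probes from low Rec10 at their own sites. Paired with their bright matches, the outer segments were lower by -0.23 (SD 0.36), less than the spread over pairs. Most of the low level may therefore be a property of bright, repeated probes. On the 15 single-site probes of the segments it was -0.19. Loess gave -0.21, but it removes the mean ratio at each brightness by construction and so cannot test brightness. Lower Rec10 on wild type pericentromeres stays open as an untested hypothesis.

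The second pattern is the higher level of the outer segments in clr4Δ 3.5 h than in wild type 3.5 h (0.55). The change did not lie in Cy5, the likely input, alone, since Cy3 differed by 0.45 (SD 0.23) and Cy5 by -0.15 (SD 0.19), and a general shrinkage of the clr4Δ ratios left an excess of 0.39 (SD 0.21, above 0 for 195 of 195 probes), against 0.09 (SD 0.14) for Tf2 probes. A shift of all several-site probes or of all bright probes is argued against as the whole cause. Several-site probes elsewhere moved by 0.355 of the outer-segment difference and bright single-site probes by 0.309 of it. Neither set was limited to the arms, and the several-site set includes subtelomeric probes. A shift at the chromosome ends without clr4 would count in these shares. They therefore do not give the part owed to brightness or repetition. Mitochondrial probes, brighter still, moved by 0.41 (-0.0893 under loess), which leaves the point on brightness less settled. Tf2 probes, bright and repeated, moved by 0.31 (SD 0.13), so bright repeats may give a part of the difference. The 15 single-site probes of the outer segments moved by 0.45 (SD 0.32, 14 of 15 above 0). Their medians were 0.46 on chromosome I and 0.32 on chromosome II, with 0.89 on 4 adjacent probes at the left edge of centromere II. Sites were counted by exact matches only, so binding of near-identical repeat copies to these probes was not excluded. That more Rec10 lay on these repeats without clr4 is a hypothesis, found and examined on the same arrays, and 1 array per group leaves an array-specific effect open.

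The third pattern is the smaller number of domains in clr4Δ 3.5 h (19 against 60). Shrinkage of all ratios by the factor found on arm probes outside the domains (0.862) is argued against as the sole cause, since the threshold multiplied by it gave 29 domains, not the 40 that would come within 1.5 times of wild type. That factor is a regression slope, which noise also lowers, and it does not measure enrichment at the peaks, so a less efficient precipitation stays open. Over the 60 domains the log2 level in clr4Δ divided by that in wild type had a median of 0.64 and quartiles 0.136 apart (0.565 and 0.701), a narrow range of log2 quotients and not 1 fold difference, as the highest domain read 2.27 and 1.65 and the lowest 1.03 and 0.88. An earlier stage of meiosis or an effect of clr4 on all peaks could also give it, and the design with 1 array per group does not separate them. The 60 domains already differed at 0 h, with medians of 0.04 in wild type and -0.29 in clr4Δ. The quotients at 3.5 h do not take this earlier difference out.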

How the results depend on the processing

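Having 1 array per group is the limit that no alternative lifts. No paired analysis was possible because each group holds 1 array and the labels give no culture or replicate number that would pair arrays. Of the alternatives, those on the domain threshold times the arm slope, on outer segments, on the mat3 interval and on gene counts were added after the data were seen. By the scanner's flags 1 probe was not well above background and 0 were saturated, although many sizes depended on the background correction. For region and list values, a change of sign was counted only where the main value lay outside the central range, and otherwise the size of the move alone was counted. Over region values, 931 of 993 alternative values moved by less than the spread over probes, 41 moved by more and 21 changed sign, 5 of them under the turned sign, by construction. For gene lists the numbers were 1030, 9 and 5 of 1044, for named genes 636, 72 and 0 of 708, and for named domains 80, 10 and 0 of 90, the 10 all under normexp, which gave 2.74, 3.32, 3.41, 2.77, 3.43, 3.44, 3.42, 3.29, 3.21 and 3.25 in the main order. Filters on dim or non-uniform probes, centring on arm probes, means, the authors' value table and other flank sizes moved none of the region and list values by more than that spread. The authors' table gives no mitochondrial value, and leaving out several-site probes gives none for centromeric repeats, the mat3 genes or Tf2. Except where a construction is named, the cause was not tested.

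Loess, which removes the mean ratio at each brightness by construction, changed the largest number of region and list values, and normexp the largest number of named genes, named domains and gene counts. Under loess centromere I read 0.0202, -0.15, -0.10 and 0.12 (main: -0.36, -0.90, -0.51 and -0.22) in wild type 0 h and 3.5 h and clr4Δ 0 h and 3.5 h. In the same order centromere II read 0.0236, -0.20, -0.14 and 0.12, centromere III 0.0206, -0.17, -0.11 and 0.10, the outer segments 0.0025, -0.21, -0.15 and 0.14, Tf2 0.0104, -0.0229, 0.29 and -0.12, and mitochondrial probes -0.089, 0.87, -0.99 and 0.80. All centromeric repeats read 0.028 in wild type 0 h and subtelomeres 0.0039 in clr4Δ 0 h. Wild type 3.5 h minus 0 h became -0.23 on centromere II, -0.19 on centromere III, -0.22 in the outer segments, -0.0333 for Tf2 and 0.93 for mitochondrial probes. For clr4Δ minus wild type, mitochondrial probes gave -0.0893 at 3.5 h, and Tf2 gave -0.10 at 3.5 h, 0.28 at 0 h and -0.38 for the difference of the changes. The mat3 genes read 0.0721 in wild type 0 h, 0.22 in wild type 3.5 h and 0.12 in clr4Δ 3.5 h, with differences of 0.18 (wild type over time), 0.47 (clr4Δ over time) and -0.12 (genotypes at 3.5 h).

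Normexp gave clr4Δ minus wild type at 3.5 h of 0.79 on centromere II and 0.83 in the outer segments. The mat3 genes read 0.0778, 0.0119, -0.59 and 0.0708 in the order above, with -0.0576 and 0.66 over time in wild type and clr4Δ, -0.67 between genotypes at 0 h and 0.65 for the difference of the changes, and the mat3 interval 0.70 over time in clr4Δ. Mitochondrial probes read 0.0073 in wild type 3.5 h and -1.95 in clr4Δ 0 h, with 0.66 and 2.39 over time and -1.28 between genotypes at 0 h. Ribosomal protein genes in clr4Δ 0 h read 0.0019, and histone genes -0.43 and -0.11 in clr4Δ at 0 h and 3.5 h, -0.21 between genotypes at 0 h and 0.13 for the difference of the changes. Counts of genes at 0.5 under normexp were 217 higher and 308 lower (main: 106 and 30) over time in wild type, 144 and 215 (61 and 16) in clr4Δ, 15 and 39 (0 and 9) between genotypes at 3.5 h, 258 and 242 (69 and 66) at 0 h, and 320 and 358 (87 and 113) for the difference of the changes. With arrays scaled to one median absolute deviation, wild type over time gave 48 lower and genotypes at 3.5 h 2 and 14. With arm centring 2 genes were higher between genotypes at 3.5 h, under loess 14 were lower, and with means 4 were higher and 15 lower, and 17 lower over time in wild type (15 without several-site probes).

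Without several-site probes, which leaves 15 probes in the outer segments, these read 0.0057, -0.19, -0.039 and 0.23, with -0.18 over time in wild type, and subtelomeres 0.021 in clr4Δ 0 h. Scaled arrays gave -1.16 for mitochondrial probes between genotypes at 0 h and -0.64 for Tf2 over time in wild type. Leaving out centromere III moved the outer segments over time in wild type to -0.31. With the sign turned, all centromeric repeats gave 0.38 and -0.19 over time in wild type and clr4Δ, -0.43 and 0.17 between genotypes at 3.5 h and 0 h, and -0.60 for the difference of the changes. Single arm probes matched on signal, in place of windows, moved 6 of 60 percentiles across the range's limits: centromere I between genotypes at 0 h to 3.63, single-site centromeric probes and flanks over time in wild type to 0.19 and 0.01, flanks for the difference of the changes to 99.9, and the mat3 interval over time in wild type to 100 and for the difference of the changes to 99.1. Because neighbouring probes correlate, a range from single probes is too narrow for a region, and windows carry more weight.

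A domain threshold of 0.5 gave 40 domains in wild type 0 h, 174 in wild type 3.5 h, 2 in clr4Δ 0 h and 140 in clr4Δ 3.5 h, with 109 and 110 shared at 3.5 h. A threshold of 1.5 gave 21 and 3 at 3.5 h, with 3 and 3 shared. Runs of 6 probes gave 37 and 8, with 8 and 8 shared, and the threshold times the arm slope 29 in clr4Δ 3.5 h.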

Other observations

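Chosen only after the data were seen were the tRNA neighbourhoods, the central domains, and the single-site probes of the outer segments described here.

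Single-site probes within 500 bp of tRNA genes on the arms (460 probes), sites where RNA polymerase III works, stood above the arms at 3.5 h, with medians of 0.21 (SD 0.19) in wild type and 0.24 (SD 0.36) in clr4Δ, against 0.06 (SD 0.34) and 0.01 (SD 0.25) at 0 h. Their difference between clr4Δ and wild type at 3.5 h was 0.02 (SD 0.31). The dimmest arm probes read as high at 3.5 h (0.20 and 0.24), and the brightness of the probes near tRNA genes was not compared. Without an untagged control, non-specific signal at these sites was not measured. Near centromeric tRNA genes (39 probes) the medians were 0.12 and 0.13 in wild type and 0.12 and 0.23 in clr4Δ at 0 h and 3.5 h. Central domains, where the kinetochore forms, stood above the arms on all 4 arrays, with 0.16 and 0.20 in wild type and 0.12 and 0.21 in clr4Δ, each above the 97.5 percentile of windows and already so at 0 h. At 3.5 h, kinetochore and pericentromere protection genes had a median of 0.09 in wild type (percentile 98.8), while at 0 h heterochromatin islands stood at 0.14 in wild type (percentile 97.9) and histone genes at -0.20 (percentile 1.13) and ribosomal protein genes at -0.06 (percentile 0.53, but 0.0019 under normexp) in clr4Δ.

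The outer segments hold 15 probes that match 1 site, on chromosomes I and II. Their medians were 0.01 in wild type 0 h, -0.19 in wild type 3.5 h, -0.04 in clr4Δ 0 h and 0.23 in clr4Δ 3.5 h. Between clr4Δ 3.5 h and wild type 3.5 h they differed by 0.45 (SD 0.32, 14 of 15 above 0), above all windows of 15 probes, and the difference of the time changes was 0.57 (SD 0.27, 15 of 15 above 0, percentile 99.9). Wild type 3.5 h minus 0 h gave -0.18 (SD 0.23, percentile 12.8), inside the range of windows. At the left edge of centromere II, 4 adjacent probes (II 1603139 to 1603682) read -0.24 (SD 0.13) in wild type 3.5 h and 0.65 (SD 0.18) in clr4Δ 3.5 h.

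On the arms the brightest single-site probes had the lowest ratios on all 4 arrays, although in clr4Δ 0 h the ratio first went up with brightness, to 0.0195. From the dimmest class (more than 0.5 below the array's median brightness on the log2 scale) to the brightest (more than 1.5 above it, 79 probes) it went from 0.20 to -0.83 in wild type 3.5 h and from 0.24 to -0.59 in clr4Δ 3.5 h, and from 0.05 to -0.49 and from -0.03 to -0.52 at 0 h.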
